A study of Homo sapiens with 10 samples.

How the data were processed

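RNA of human blood monocytes and of macrophages grown from them was measured on Affymetrix HG-U133 Plus 2.0 arrays, 10 in all, 2 for each of 5 conditions. The conditions were fresh monocytes, culture with M-CSF, M-CSF with IFN-gamma, M-CSF with Pam3Cys, and M-CSF with both. The cells came from 2 donors, and each donor gave 1 array per condition. Groups and replicate numbers were taken from the sample labels.

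The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set, as the authors made them with MAS5 per the submitters' processing notes, and its version is not given in the sources used here. GeneSpring is named per the labels for the authors' later analysis, and none of its output was used here. On every array the mean of the middle 96% of values was 500, so the arrays had been scaled to a common trimmed mean before deposit. Such a scaling can shift most genes on an array when bright genes change. Each array's median lay between 56.3 and 77.1, and no further scaling was applied. M-CSF+IFN replicate 1 had the lowest median and the lowest signals of the spike-in controls, 31068 for cre and 840 for bioB. On the other arrays these were 42737 to 63186 and 1111 to 1995. No array was a copy of another: the Pearson r of a pair was at most 0.924, and at most 3 probe sets had exactly the same signal on both arrays. The number of arrays limits the precision, with 5 residual degrees of freedom.

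The table held 54675 probe sets, of which 62 were control probe sets. Through the platform annotation given, 41097 had 1 gene, 1801 several and 11715 none, and only those with 1 gene were used. Symbols were updated by Entrez identifier for 41043. No genome build was used here, so no coordinates are given. Another 100 probe sets were left out by a rule on X-inactivation, Y-linked, presence-absence and highly polymorphic genes. Of the 19725 genes with a probe set, each was represented by the probe set with the highest mean log2 value. Genes were kept where at least 2 of the 10 arrays reached the array's median, which left 13678.

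Values were analysed as log2(signal + 17.24), the constant being the median over arrays of the 25th percentile, so fold changes of dim genes are understated. limma 3.58.1 in R 4.3.3 was fitted to all 10 arrays with 1 coefficient per condition, and eBayes used a prior variance that follows the mean signal. All adjusted p values are from limma with Benjamini-Hochberg adjustment at 0.05, two-sided, over the genes of 1 comparison. The comparisons, contrasts, alternatives and 36 gene lists were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. Over the 7 comparisons 85 list calls were made, and none held with an estimated correlation. In simulated data a list shifted by 1 log2 had an adjusted p of 0.00761 with an estimated correlation, which does not show what that test can call at the correlations of the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

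The fit was tested on simulated data with 13678 genes, of which 100 were changed 2-fold and 100 changed 4-fold. For the IFN-gamma effect in M-CSF culture 24% of the 2-fold and 73% of the 4-fold changes were recovered, with 4 false calls among 13478 unchanged genes. For the Pam3Cys effect under IFN-gamma these were 28%, 67% and 4, and for the interaction 4%, 39% and 1. Fewer genes were changed there than passed in the data, which makes the adjusted threshold stricter. The rates may therefore understate what the real comparisons could call.

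Replicates of 1 number come from the same donor per the labels. Deviations of such arrays from their group means correlated across genes in each of the 10 pairs of conditions, with r between 0.11 and 0.26 (median 0.18). The donor was left out of the model as planned and fitted as a block in an alternative. Relations between comparisons that share arrays were set beside 100 simulated sets of unchanged groups. With groups of 2 no test of a single array against its group and no test of other splits of the samples was made.

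Genes were named by a rule: per comparison the 6 largest rises and 6 largest falls that passed, changed at least 2-fold and went the same way in both donors, up to 4 members of each list by adjusted p, and 15 fixed genes, of which 14 were measured and 1 is not analysed here. The rule named 1084 pairs of gene and comparison, 742 of them past the threshold. Genes for the text were picked from a selection of 322 of these pairs, 306 past the threshold, which was made after their values were seen and before any alternative was computed. At least 1 alternative or left-out array changed the call of 226 of the 742 pairs and of 49 of the 306, so the selection is more stable than the whole.

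Alternatives were a pseudocount of 1 or 4 times larger, no filter or a filter at the 70th percentile, quantile normalization, scaling to a common median, the mean over probe sets of a gene, leaving out probe sets with the suffix _x_ or _s_, a donor block, a prior variance without trend, fitting only the arrays compared, fry for the lists, and leaving out each array in turn. A second probe set for HES1 was added after the data were seen. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Median scaling moved the median log2 change of all genes from 0.14 to -0.15 for M-CSF culture against fresh monocytes, from 0.10 to -0.12 for culture with M-CSF and IFN-gamma, from -0.12 to 0.20 for Pam3Cys, and from -0.13 to 0.15 for Pam3Cys under IFN-gamma. Quantile normalization moved that for Pam3Cys to -0.02. The shift of other comparisons was under 0.1.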

Results

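Transcript levels were measured in primary human monocytes on 10 arrays, with 5 conditions in each of 2 donors. Monocytes carrying the surface protein CD14 were selected with magnetic beads from blood, and RNA was taken from them fresh or after culture for 30 h. All cultures held 10 ng/mL M-CSF, the growth factor that drives monocytes to become macrophages, in medium with 10% serum. IFN-gamma, a cytokine of T and NK cells that activates macrophages, was added at 100 U/mL to 2 of the 4 culture conditions. Pam3Cys, a synthetic bacterial lipopeptide that activates Toll-like receptor (TLR) 2, was added at 10 ng/mL for the last 6 h to 2 of the 4. Each condition had n = 2 arrays, 1 per donor, and this number limits the precision. The median signal of an array lay between 56.3 and 77.1. The median absolute difference between the 2 donors of a condition was 0.24 to 0.32 on the log2 scale. Changes are given below as log2 fold changes ± SE with n = 2 per condition, signals as means ± SD with n = 2, and a gene is said to rise or fall only where the limma adjusted p was under 0.05.

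The first comparison asked how monocytes changed during culture with M-CSF. No culture without M-CSF was measured. Effects of M-CSF, of culture itself and of the isolation of the fresh cells therefore cannot be told apart. Genes of macrophages rose steeply. SELENOP, which encodes a selenium transport protein, went from a signal of 18.0 ± 0.868 to 28598 ± 2887 (log2 change 9.66 ± 0.38). SPP1, the secreted matrix protein osteopontin, changed by 7.93 ± 0.22, the glycoprotein gene GPNMB by 7.92 ± 0.29 and RNASE1, a secreted ribonuclease, by 7.89 ± 0.36. The cystine transporter gene SLC7A11 rose by 7.78 ± 0.29 and the formyl peptide receptor gene FPR3 by 7.47 ± 0.20. Of 24 measured macrophage differentiation genes, 17 rose, 1 fell and 6 did not pass (19 higher and 1 lower adjusted over the list alone), among them the mannose receptor gene MRC1 at 5.61 ± 0.30 (limma camera adjusted p = 2.32e-08, and adjusted p = 0.0711 with an estimated correlation). CSF1R, the M-CSF receptor, rose by 1.64 ± 0.19 and the scavenger receptor gene CD163 by 1.06 ± 0.22. Of 16 macrophage transcription factor genes, 6 rose, 5 fell and 5 did not pass (7 higher and 5 lower adjusted over the list alone, limma camera adjusted p = 0.657, and adjusted p = 0.769 with an estimated correlation), and the list's median turned from 0.19 to -0.10 with median scaling. Among them MAF was at 5.26 ± 0.20, BHLHE41 at 4.60 ± 0.28 and KLF4 at -3.83 ± 0.18.

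Genes of fresh monocytes and of early cell activation fell in the same cultures. Of 19 measured immediate early genes, which respond to stimuli within minutes, 18 fell and 1 did not pass (0 higher and 18 lower adjusted over the list alone, limma camera adjusted p = 7.00e-17, and adjusted p = 0.0711 with an estimated correlation). FOSB changed by -7.91 ± 0.51, EGR1 by -6.87 ± 0.51, IER2 by -3.59 ± 0.18 and JUNB by -3.10 ± 0.16. Of 16 monocyte-enriched genes, 10 fell and 6 did not pass (0 higher and 12 lower adjusted over the list alone, limma camera adjusted p = 2.32e-08, and adjusted p = 0.182 with an estimated correlation). The calcium-binding protein genes S100A12 and S100A9 changed by -6.40 ± 0.37 and -3.40 ± 0.25, and the surface receptor gene CD93 by -3.65 ± 0.21. G0S2, an inhibitor of fat breakdown, changed by -7.40 ± 0.43 and the growth factor gene HBEGF by -5.62 ± 0.39. The cytokine genes IL6 and IL1B fell, with changes of -2.74 ± 0.21 and -3.09 ± 0.42.

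Several metabolic and housekeeping groups also moved with culture. Of 23 lysosomal genes, 15 rose, 1 fell and 7 did not pass (16 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 2.12e-05, and adjusted p = 0.464 with an estimated correlation), with the cholesterol transporter gene NPC1 at 3.47 ± 0.19 and the proton pump subunit gene ATP6V0D2 at 5.24 ± 0.47. Of 10 oxidative stress response genes, 8 rose and 2 did not pass (8 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.34e-05, and adjusted p = 0.0711 with an estimated correlation), including TXNRD1 at 2.02 ± 0.13 and PRDX1 at 1.96 ± 0.17. Of 15 cell cycle genes, 6 rose and 9 did not pass (6 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0456, and adjusted p = 0.384 with an estimated correlation). The replication genes MCM6 and PCNA rose by 3.45 ± 0.22 and 2.41 ± 0.21. Of 17 ribosomal protein genes, 15 fell and 2 did not pass (0 higher and 15 lower adjusted over the list alone, limma camera adjusted p = 7.08e-07, and adjusted p = 0.464 with an estimated correlation), for example RPS9 at -0.92 ± 0.17. The antigen processing gene TAP2 and its regulator NLRC5 changed by -1.83 ± 0.24 and -2.50 ± 0.32, and IRF1, a transcription factor of the interferon response, by -3.09 ± 0.17.

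In all, 4393 of 13678 genes passed the limma test between M-CSF culture and fresh monocytes, 2810 higher and 1583 lower, and 2794 of them had changed at least 2-fold. With each array scaled to the same median, the split was 1856 higher and 2578 lower. The ratio of the 3' to the 5' probe set of GAPDH, a measure of RNA integrity, was 1.02 and 1.08 on the fresh arrays and 1.16 and 1.33 on the M-CSF arrays. HES1, a transcriptional repressor and target of the Notch receptor pathway, had a change of -0.06 ± 0.37 (limma adjusted p = 0.925) at its brighter probe set. The sign of this change turned without fresh replicate 1 (0.03) or M-CSF replicate 1 (0.35). At its other probe set it fell by 2.40 ± 0.46 (limma adjusted p = 0.00334 in a fit of all probe sets). IL10 rose by 0.99 ± 0.28 (limma adjusted p = 0.0184), a call that was lost when fresh replicate 1, fresh replicate 2, M-CSF replicate 1 or M-CSF replicate 2 was left out (limma adjusted p = 0.057, 0.097, 0.064 and 0.099) and with median scaling (0.076).

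The second comparison asked what IFN-gamma changed in M-CSF culture without Pam3Cys. Genes of the interferon response rose. IDO1, an enzyme that degrades tryptophan, went from a signal of 169 ± 86.8 to 25605 ± 6752 (log2 change 7.16 ± 0.39). The chemokine genes CXCL9 and CXCL10, which attract T cells, rose by 6.58 ± 0.27 and 4.74 ± 0.41, the guanylate-binding protein gene GBP5 by 7.26 ± 0.42 and ANKRD22 by 7.97 ± 0.33. CD274, which encodes the checkpoint ligand PD-L1, rose by 5.50 ± 0.21. Of 19 measured IFN-gamma response genes, 17 rose and 2 did not pass (18 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.32e-32, and adjusted p = 0.0982 with an estimated correlation). Of 20 type I interferon response genes, 12 rose and 8 did not pass (16 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.02e-10, and adjusted p = 0.420 with an estimated correlation), for example IFIT3 at 2.62 ± 0.30 and ISG20 at 3.07 ± 0.43. Of 12 MHC class I processing genes, 8 rose and 4 did not pass (10 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 7.94e-13, and adjusted p = 0.166 with an estimated correlation), with the peptide transporter gene TAP1 at 2.86 ± 0.18 and the proteasome subunit gene PSMB9 at 3.18 ± 0.23.

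Many genes that M-CSF culture had raised were lower with IFN-gamma. SELENOP went to a signal of 12.8 ± 2.46 (log2 change -9.90 ± 0.38), SPP1 changed by -3.37 ± 0.22, the scavenger receptor gene CD163 by -2.17 ± 0.22, FABP4, a fatty acid carrier, by -6.13 ± 0.55 and MAF by -1.69 ± 0.20. The matrix protein gene FN1 and CSF1R changed by -7.39 ± 0.79 and -0.97 ± 0.19. Of 24 macrophage differentiation genes, 2 rose, 11 fell and 11 did not pass (3 higher and 13 lower adjusted over the list alone, limma camera adjusted p = 9.00e-05, and adjusted p = 0.248 with an estimated correlation). MRC1 fell by 1.49 ± 0.30 (limma adjusted p = 0.00711), a call lost without M-CSF replicate 1 (adjusted p = 0.067) or M-CSF+IFN replicate 2 (adjusted p = 0.061). PPBP, a chemokine best known from platelets, changed by -9.26 ± 0.36. The clotting factor gene F13A1, which culture had not raised, fell by 7.05 ± 0.32.

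Cytokine and chemokine genes moved in both directions. IL6 rose by 2.07 ± 0.21, TNF by 2.45 ± 0.37 and IL15 by 2.57 ± 0.29, while IL10, an anti-inflammatory cytokine, changed by -2.47 ± 0.28. Of 17 inflammatory cytokine genes, 4 rose and 13 did not pass (5 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0254, and adjusted p = 0.619 with an estimated correlation). The neutrophil-attracting chemokine genes CXCL3 and CXCL8 changed by -3.44 ± 0.44 and -1.82 ± 0.32, and CCL8 by 4.42 ± 0.41. SOCS1, an inhibitor of interferon signalling, rose by 4.09 ± 0.26, and the costimulatory receptor gene CD40 by 2.68 ± 0.18. Of 13 cholesterol synthesis and uptake genes, 5 rose and 8 did not pass (8 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 3.29e-06, and adjusted p = 0.420 with an estimated correlation), such as SQLE at 1.76 ± 0.23. TLR2 had a change of 0.52 ± 0.15 (limma adjusted p = 0.0401), and this call was lost when any array but M-CSF+IFN replicate 1 or the 2 M-CSF+Pam arrays was left out (adjusted p = 0.050 to 0.25, highest without M-CSF replicate 1).

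HES1 went from a signal of 289 ± 120 to 7.74 ± 2.80 with IFN-gamma (log2 change -3.56 ± 0.37, limma adjusted p = 9.51e-05). This is the value of the brighter probe set. At the other HES1 probe set with a mean signal above the array median the change was -0.81 ± 0.46 (limma adjusted p = 0.431 in a fit of all probe sets). HEY1, another Notch target, had a change of -0.26 ± 0.39 (limma adjusted p = 0.751), which turned to 0.21 without M-CSF+IFN replicate 1. In all, 1668 of 13678 genes passed the limma test, 857 higher and 811 lower, and 1022 changed at least 2-fold. The count fell to 697 without M-CSF replicate 1, 973 without M-CSF replicate 2 and 877 without M-CSF+IFN replicate 2, and to 1055 with a variance prior that did not follow the signal.

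**Figure D1:**
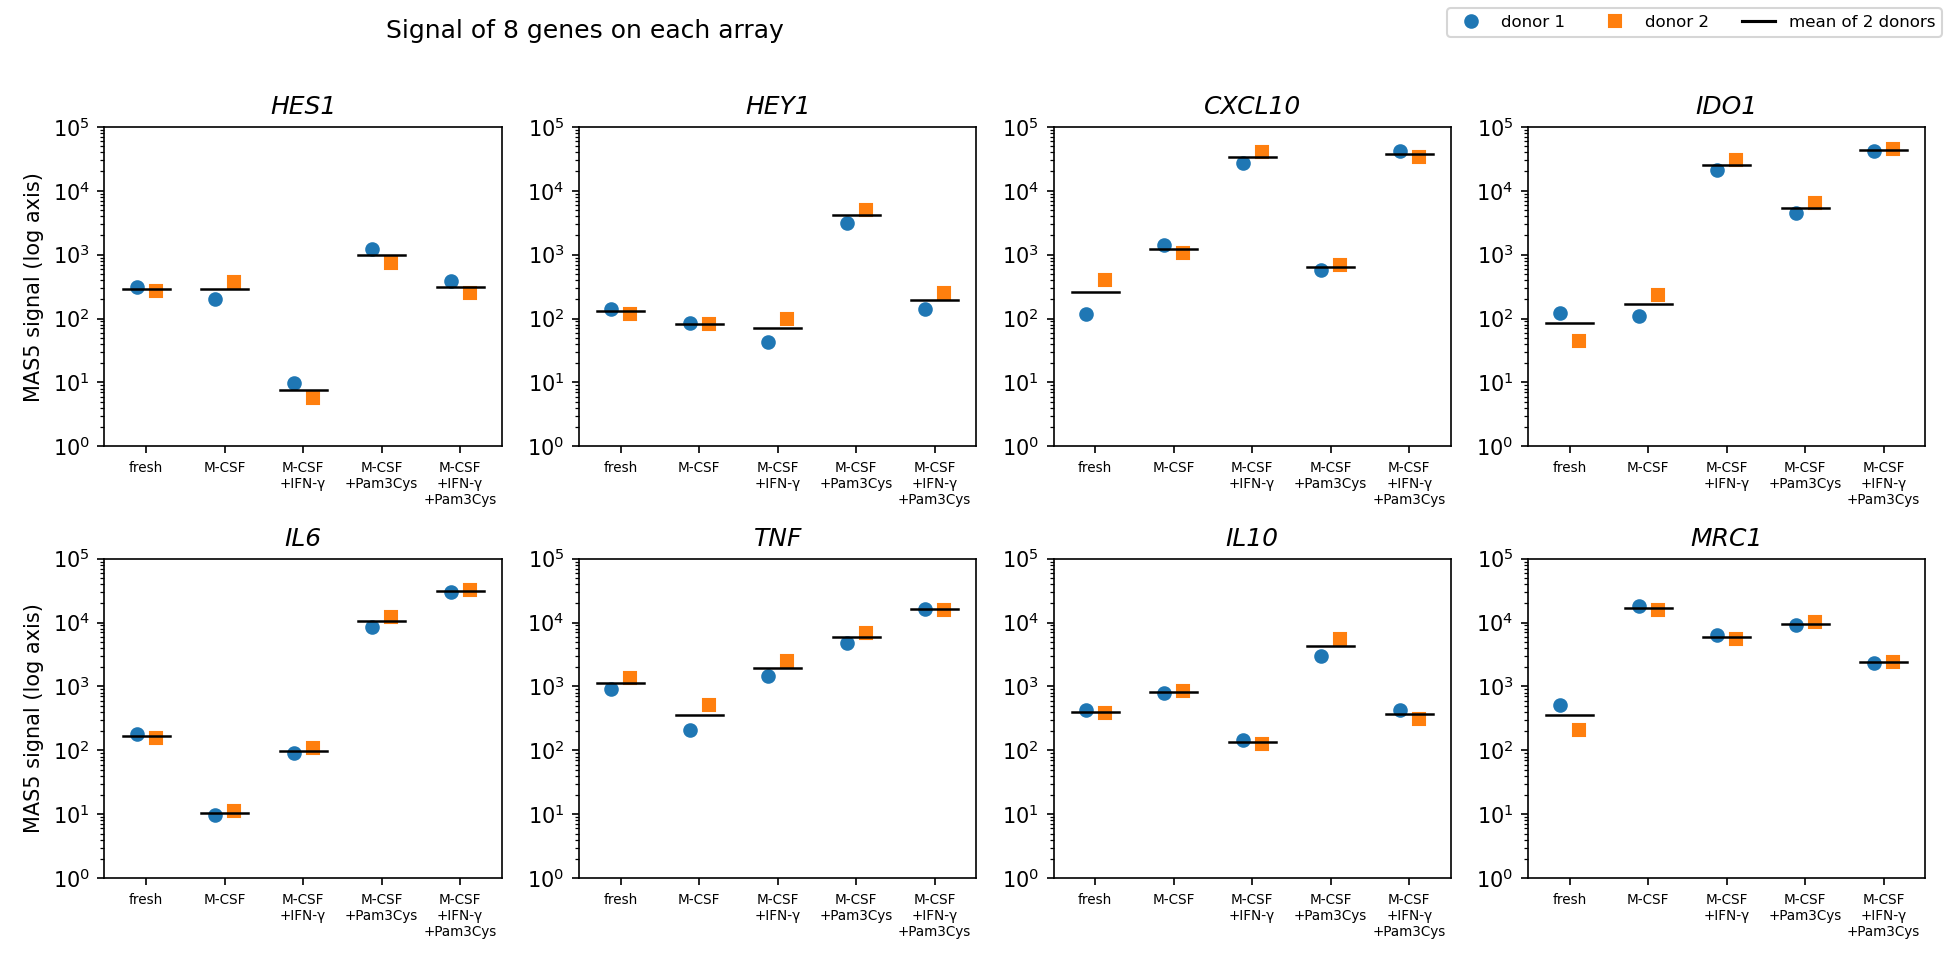
MAS5 signal (log axis) of 8 genes on each of the 10 arrays, by condition. Circles and squares are the 2 donors and the bar is their mean. HES1, shown at its brighter probe set, has its lowest mean, 7.74, in M-CSF with IFN-gamma, and HEY1 its highest, 4105, in M-CSF with Pam3Cys.

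The third comparison was of Pam3Cys for 6 h against none in M-CSF culture. Inflammatory genes rose from near background to high signal. INHBA, a subunit of the growth factor activin, went from 20.7 ± 23.3 to 28483 ± 7373 (log2 change 9.68 ± 0.37), the chemokine gene CCL20 from 14.2 ± 1.01 to 13214 ± 768 (8.71 ± 0.21) and IL6 from 10.5 ± 0.910 to 10442 ± 2502 (8.54 ± 0.21). Of 16 measured inflammatory chemokine genes, 16 rose (16 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 4.24e-13, and adjusted p = 0.130 with an estimated correlation), with CXCL1 at 5.76 ± 0.52 and CCL5 at 3.40 ± 0.26. Of 17 inflammatory cytokine genes, 13 rose and 4 did not pass (13 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.27e-10, and adjusted p = 0.237 with an estimated correlation), with TNF at 4.06 ± 0.37 and IL12B at 5.79 ± 0.50. IL1A was at 8.04 ± 0.51 on its brightest probe set and at 0.39 (limma adjusted p = 0.34) on the brightest of those without the _x_ or _s_ suffix that marks probe sets shared between transcripts.

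Targets of NF-kappaB and feedback genes rose too. Of 17 NF-kappaB subunits and targets, 16 rose and 1 did not pass (16 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.01e-15, and adjusted p = 0.237 with an estimated correlation), including the subunit gene NFKB1 at 2.91 ± 0.15, the prostaglandin synthase gene PTGS2 at 5.45 ± 0.30 and CD40 at 4.02 ± 0.18. Of 20 genes of negative feedback on TLR signalling, 15 rose, 1 fell and 4 did not pass (15 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 4.19e-12, and adjusted p = 0.130 with an estimated correlation), with TNIP3 at 8.90 ± 0.39, SOCS3 at 4.69 ± 0.24, the phosphatase gene DUSP2 at 3.96 ± 0.19 and IL10 at 2.30 ± 0.28. Of 18 TLR signalling components, 3 rose, 7 fell and 8 did not pass (4 higher and 7 lower adjusted over the list alone, limma camera adjusted p = 0.964, and adjusted p = 0.997 with an estimated correlation), but 7 rose and 5 fell with median scaling. TLR2, the receptor for Pam3Cys, rose by 1.61 ± 0.15, while TLR4 and TLR5 changed by -1.87 ± 0.17 and -2.90 ± 0.24. Of 19 IFN-gamma response genes, 11 rose, 4 fell and 4 did not pass in the absence of added IFN-gamma (11 higher and 4 lower adjusted over the list alone, limma camera adjusted p = 1.15e-04, and adjusted p = 0.386 with an estimated correlation). Rises included CD274 at 6.43 ± 0.21, IDO1 at 4.91 ± 0.39 and SOCS1 at 4.35 ± 0.26. Of 20 type I interferon response genes, 1 rose, 5 fell and 14 did not pass (1 higher and 5 lower adjusted over the list alone, limma camera adjusted p = 0.492, and adjusted p = 0.997 with an estimated correlation), and the list's median turned from -0.27 to 0.04 with median scaling. IFIT1 was at -2.04 ± 0.45 and IFIT2 at -2.73 ± 0.41. CXCL10 had a change of -0.93 ± 0.41 (limma adjusted p = 0.105), and passed without fresh replicate 1 or fresh replicate 2 (limma adjusted p = 0.0098 and 0.0099).

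Of 7 measured Notch target genes, 3 rose and 4 did not pass (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0338, and adjusted p = 0.296 with an estimated correlation). HEY1 went from a signal of 83.4 ± 1.56 to 4105 ± 1356 (log2 change 5.32 ± 0.39) and HES1 from 289 ± 120 to 982 ± 349 (1.72 ± 0.37, and 3.68 ± 0.46 at its other probe set). NRARP changed by 1.36 ± 0.38 (limma adjusted p = 0.0151), a call lost without M-CSF replicate 1 (0.052), M-CSF replicate 2 (0.080) or M-CSF+Pam replicate 1 (0.11). The Notch coactivator gene MAML3 and the receptor gene NOTCH2 changed by -5.14 ± 0.25 and -1.08 ± 0.13. Of 12 matrix metalloproteinases and inhibitors, 7 rose, 1 fell and 4 did not pass (7 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 0.0335, and adjusted p = 0.386 with an estimated correlation), with MMP7 at 4.04 ± 0.70 and the inhibitor gene TIMP2 at -2.51 ± 0.20.

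Genes that fell with Pam3Cys included GPR34, a lysophospholipid receptor, at -8.72 ± 0.42, the iron exporter gene SLC40A1 at -6.06 ± 0.45, the retinol dehydrogenase gene DHRS9 at -5.78 ± 0.16 and PDK4, a brake on pyruvate oxidation, at -5.48 ± 0.60. CIITA, the master regulator of MHC class II genes, changed by -3.87 ± 0.21 and HLA-DMB by -2.12 ± 0.25. Of 10 MHC class II presentation genes, 0 rose, 4 fell and 6 did not pass (0 higher and 4 lower adjusted over the list alone, limma camera adjusted p = 0.241, and adjusted p = 0.809 with an estimated correlation), but 3 rose and 3 fell with median scaling. CD14 and CD163 changed by -1.31 ± 0.28 and -1.14 ± 0.22. In all, 4601 genes passed the limma test, 1777 higher and 2824 lower, and 3034 changed at least 2-fold. The split was 3003 higher and 1912 lower with each array scaled to the same median. The 3' to 5' ratio of GAPDH was 1.13 and 1.52 on the arrays with Pam3Cys and 1.16 and 1.33 on those without.

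The same stimulus was then compared with none in cultures that held IFN-gamma. CCL20 rose by 9.07 ± 0.21, IL6 by 8.09 ± 0.21, INHBA by 7.92 ± 0.37, CXCL1 by 6.84 ± 0.52 and IL12B, a subunit of the cytokines IL-12 and IL-23, by 6.75 ± 0.50. IL1A was at 7.88 ± 0.51 on its brightest probe set and at 0.53 (limma adjusted p = 0.22) without the probe sets of the suffixes _x_ and _s_. Of 17 inflammatory cytokine genes, 12 rose and 5 did not pass (12 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.73e-15, and adjusted p = 0.0785 with an estimated correlation). Of 16 inflammatory chemokine genes, 14 rose and 2 did not pass (15 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 7.75e-18, and adjusted p = 0.0727 with an estimated correlation). Of 17 NF-kappaB subunits and targets, 16 rose and 1 did not pass (16 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.19e-18, and adjusted p = 0.129 with an estimated correlation), including REL at 2.70 ± 0.14 and the dendritic cell marker CD83 at 2.50 ± 0.16. Of 20 negative feedback genes, 16 rose, 1 fell and 3 did not pass (17 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 6.09e-16, and adjusted p = 0.0727 with an estimated correlation), with SOCS3 at 3.33 ± 0.24 and ATF3 at 2.60 ± 0.26.

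Immediate early genes and oxidative stress genes rose with Pam3Cys under IFN-gamma. Of 19 immediate early genes, 12 rose and 7 did not pass (15 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 9.47e-11, and adjusted p = 0.0785 with an estimated correlation), for example IER3 at 3.47 ± 0.28. Of 10 oxidative stress response genes, 6 rose, 1 fell and 3 did not pass (7 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 2.65e-05, and adjusted p = 0.0727 with an estimated correlation), for example SLC7A11 at 2.81 ± 0.29 and SRXN1 at 1.89 ± 0.20. With Pam3Cys alone 7 of the immediate early genes rose, 2 fell and 10 did not pass (7 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 0.00378, and adjusted p = 0.386 with an estimated correlation). For the oxidative stress genes these were 6, 2 and 2 (6 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 0.0638, and adjusted p = 0.340 with an estimated correlation). Of 20 type I interferon response genes, 8 fell and 12 did not pass (0 higher and 11 lower adjusted over the list alone, limma camera adjusted p = 0.00772, and adjusted p = 0.929 with an estimated correlation). IFIT2 changed by -1.91 ± 0.41, a call lost without M-CSF+IFN replicate 1 (limma adjusted p = 0.056). GPR34, the transcription regulator gene TRERF1, the ADP receptor gene P2RY13 and TLR7 changed by -3.76 ± 0.42, -5.40 ± 0.50, -4.12 ± 0.49 and -2.66 ± 0.28. CXCL10 had a change of 0.17 ± 0.41 (limma adjusted p = 0.819), and its sign turned without M-CSF+IFN replicate 1 (-0.10).

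Of 7 Notch target genes, 4 rose and 3 did not pass under IFN-gamma (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.88e-04, and adjusted p = 0.0728 with an estimated correlation). HES1 rose by 3.72 ± 0.37 (3.13 ± 0.46 at its other probe set), HES4 by 3.54 ± 0.44 and NRARP, a feedback inhibitor of Notch signalling, by 2.44 ± 0.38. HEY1 rose by 1.31 ± 0.39 (limma adjusted p = 0.0322), a call lost without M-CSF+IFN replicate 1 (adjusted p = 0.22), without M-CSF+IFN+Pam replicate 2 (adjusted p = 0.22) and under 5 other settings, among them the mean over its probe sets (adjusted p = 0.093). In all, 3034 genes passed the limma test, 1047 higher and 1987 lower, and 1801 changed at least 2-fold. With each array scaled to the same median the split was 1847 higher and 1069 lower, and the total was 1822 without M-CSF+IFN replicate 1. The 3' to 5' ratio of GAPDH was 1.23 and 1.39 on the arrays with both stimuli and 1.08 and 1.27 on those with IFN-gamma alone.

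The next comparison was of IFN-gamma against none among cultures given Pam3Cys. CXCL9 went from a signal of 121 ± 35.9 to 39518 ± 2794 (log2 change 8.18 ± 0.27) and CXCL10 from 641 ± 83.2 to 37793 ± 5938 (5.84 ± 0.41). SERPING1, an inhibitor of complement, rose by 5.69 ± 0.32 and ANKRD22 by 5.69 ± 0.33. Of 19 measured IFN-gamma response genes, 15 rose and 4 did not pass (15 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.84e-21, and adjusted p = 0.238 with an estimated correlation). Of 12 MHC class I processing genes, 7 rose and 5 did not pass (9 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 8.72e-10, and adjusted p = 0.285 with an estimated correlation). Of 10 MHC class II presentation genes, 5 rose, 1 fell and 4 did not pass (6 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 5.08e-04, and adjusted p = 0.409 with an estimated correlation), with CIITA at 2.66 ± 0.21 and HLA-DMB at 1.80 ± 0.25. Of 17 inflammatory cytokine genes, 4 rose and 13 did not pass (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0229, and adjusted p = 0.717 with an estimated correlation), with IL6 at 1.62 ± 0.21 and IL15 at 2.21 ± 0.29. TNF rose by 1.48 ± 0.37 (limma adjusted p = 0.0291), a call lost when M-CSF+Pam replicate 1 or 2 or M-CSF+IFN+Pam replicate 1 or 2 was left out (adjusted p = 0.17, 0.050, 0.12 and 0.11).

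IL10 fell from a signal of 4331 ± 1820 to 374 ± 85.6 (log2 change -3.43 ± 0.28), and SLAMF1, a receptor of activated immune cells, from 8733 ± 1425 to 165 ± 104 (-5.71 ± 0.49). HEY1 fell from 4105 ± 1356 to 198 ± 80.8 (-4.27 ± 0.39). HES1 changed by -1.56 ± 0.37 (limma adjusted p = 0.0199), a call lost without M-CSF+Pam replicate 1 or M-CSF+IFN+Pam replicate 2. Its other probe set changed by -1.36 ± 0.46. In a fit of all probe sets the limma adjusted p was 0.0410 at the brighter probe set and 0.155 at the other. HES4 rose by 3.18 ± 0.44. Of 12 matrix metalloproteinases and inhibitors, 5 fell and 7 did not pass (0 higher and 6 lower adjusted over the list alone, limma camera adjusted p = 0.00163, and adjusted p = 0.409 with an estimated correlation), with MMP7 at -4.18 ± 0.70. Of 24 macrophage differentiation genes, 3 rose, 9 fell and 12 did not pass (4 higher and 11 lower adjusted over the list alone, limma camera adjusted p = 0.00869, and adjusted p = 0.409 with an estimated correlation), with MRC1 at -2.00 ± 0.30, CD163 at -2.71 ± 0.22 and FN1 at -6.12 ± 0.79. The glycolytic enzyme gene LDHA and the pattern recognition gene PTX3 changed by -1.31 ± 0.14 and -3.55 ± 0.32. In all, 1275 genes passed the limma test, 684 higher and 591 lower, and 830 changed at least 2-fold. The count was 837 without M-CSF+IFN+Pam replicate 1, 761 without M-CSF+IFN+Pam replicate 2 and 814 without the signal-dependent variance prior.

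**Figure D2:**
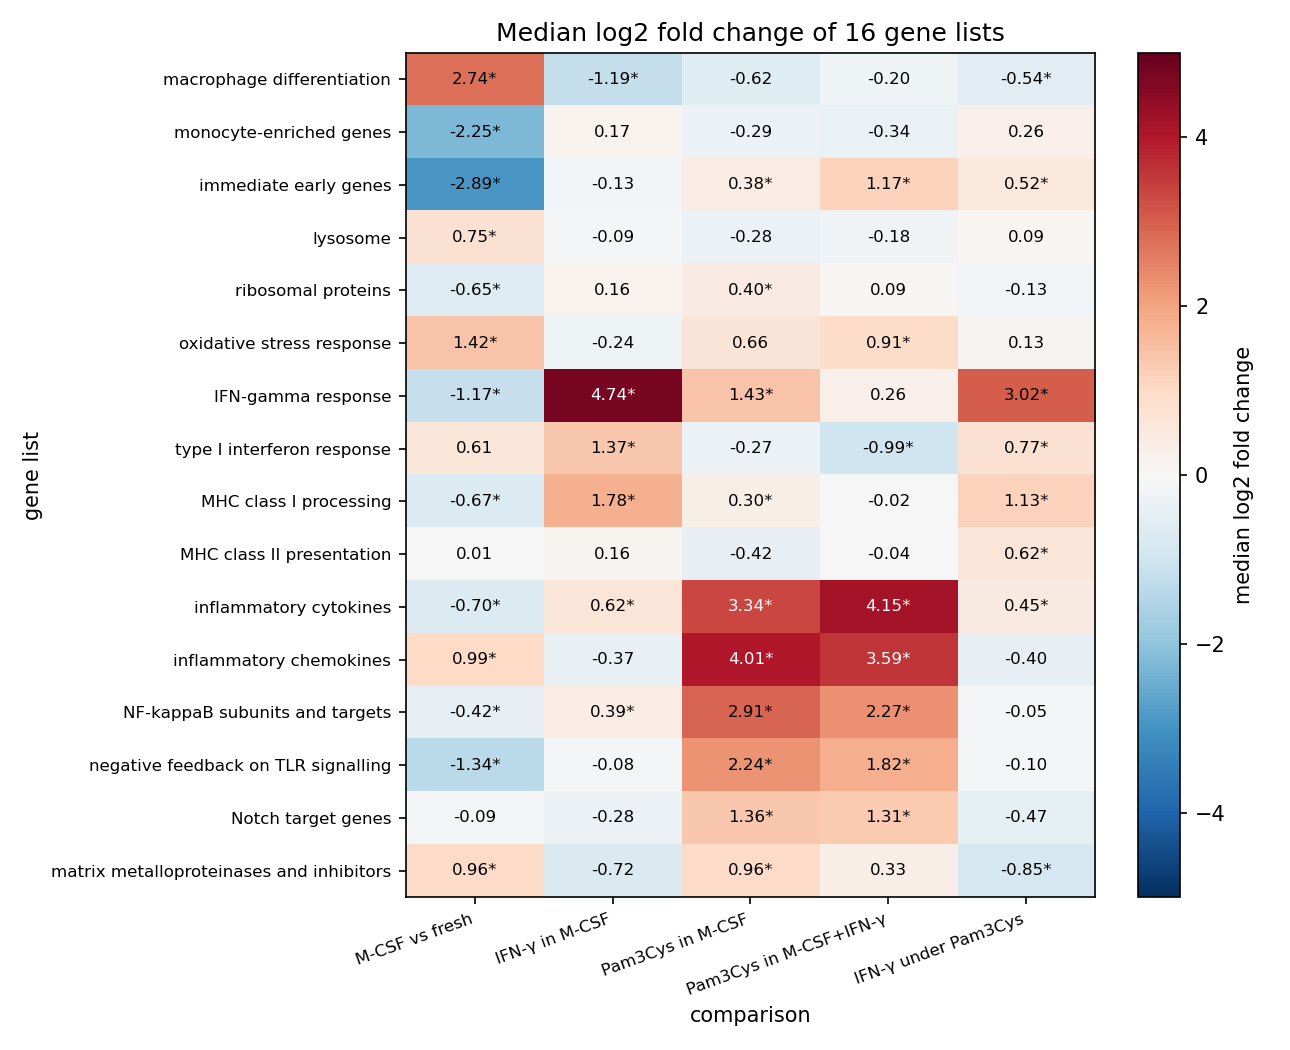
Median log2 fold change of 16 gene lists (vertical) in 5 comparisons (horizontal), with an asterisk where the limma camera adjusted p with the preset correlation was under 0.05. None of these calls held with an estimated correlation. The IFN-gamma response list has medians of 4.74 and 3.02 in the IFN-gamma comparisons, and the inflammatory chemokine list 4.01 and 3.59 in those of Pam3Cys.

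Whether IFN-gamma changed the response to Pam3Cys was tested by the interaction, the log2 effect of Pam3Cys with IFN-gamma minus that without. For CD274 the interaction was -5.36 ± 0.30: its signal went from 201 ± 55.8 to 18631 ± 2929 without IFN-gamma, and from 9672 ± 694 to 20338 ± 180 with it. SOCS1, IDO1 and the transcription factor gene IRF1 had interactions of -4.52 ± 0.37, -4.14 ± 0.55 and -1.84 ± 0.24. For CD274 and IDO1 the sum of both single rises would need a signal above 66608, the highest on any array. The top of the scale may therefore have made part of the values of CD274 and IDO1. No such check was made for the other negative interactions. Of 19 IFN-gamma response genes, 1 had a positive interaction past the threshold, 9 a negative one and 9 did not pass (2 higher and 10 lower adjusted over the list alone, limma camera adjusted p = 1.76e-05, and adjusted p = 0.576 with an estimated correlation). Negative values were also found for HEY1 at -4.01 ± 0.55, SLAMF1 at -5.46 ± 0.69, the pyrophosphatase gene PPA1 at -4.39 ± 0.35, CD93 at -3.30 ± 0.29, the transcription factor gene MYC at -2.74 ± 0.35 and CD40 at -2.69 ± 0.25. Of 17 NF-kappaB subunits and targets, 1 had a positive interaction, 3 a negative one and 13 did not pass (1 higher and 6 lower adjusted over the list alone, limma camera adjusted p = 0.00128, and adjusted p = 0.576 with an estimated correlation).

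A positive interaction was found for genes of several kinds, among them NR4A2, an immediate early nuclear receptor, at 3.48 ± 0.52. GPR34 was at 4.96 ± 0.59, F13A1 at 4.72 ± 0.46, SELENOP at 4.06 ± 0.54 and ATP6V0D2 at 3.88 ± 0.67, but the floor of the scale made at least part of each of these 4 values. IFN-gamma alone and Pam3Cys alone each lowered these genes, and the sum of both falls lay under the added constant of 17.24, so it could not show on the arrays with both stimuli. The sum of both single effects lay under that constant for 32 of the 395 genes with a positive interaction, a count made after the results were seen. It did not ask whether each stimulus alone lowered the gene. The part of the value above that constant, which stands for a signal of 0, was 2.93 for ATP6V0D2, 2.03 for F13A1, 0.52 for SELENOP and 0.36 for GPR34. Background signal above 0 was not taken off, so it may account for more of these values and touch more than those 32 genes. Of 10 MHC class II presentation genes, 2 had a positive interaction and 8 did not pass (2 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0202, and adjusted p = 0.576 with an estimated correlation), with CIITA at 2.42 ± 0.30 (1.19, limma adjusted p = 0.12, as the mean over its probe sets). For the cytokine genes IL6, TNF, IL12B and IL10 the interaction did not pass, with values of -0.45 ± 0.30, -0.97 ± 0.53, 0.96 ± 0.70 and -0.96 ± 0.40 (limma adjusted p = 0.482, 0.367, 0.530 and 0.211). For IL6 it was -1.62 (limma adjusted p = 0.018) with a pseudocount of 1 and 0.53 with 4 times the pseudocount. HES1 was at 2.00 ± 0.52 (limma adjusted p = 0.0459), a call lost when any array but M-CSF replicate 1 or M-CSF+Pam replicate 1 was left out (adjusted p = 0.066 to 0.17, highest without M-CSF replicate 2), and the value at its other probe set was -0.55 ± 0.65.

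In all, 839 of 13678 genes had an interaction past the limma threshold, 395 positive and 444 negative, and 1304 with the donors as a block. The count was 334 without M-CSF replicate 1, 449 without M-CSF replicate 2, 424 without M-CSF+IFN replicate 2, 425 without M-CSF+IFN+Pam replicate 2 and 305 without the signal-dependent variance prior. Across genes, which are not independent replicates, the Pam3Cys effects with and without IFN-gamma had a Pearson r of 0.692 and the slope of the first on the second was 0.528. Both effects called 752 genes higher, where independent lists of these sizes would share 136, and 1465 lower, where they would share 410. Another 51 genes were called in opposite directions.

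**Figure D3:**
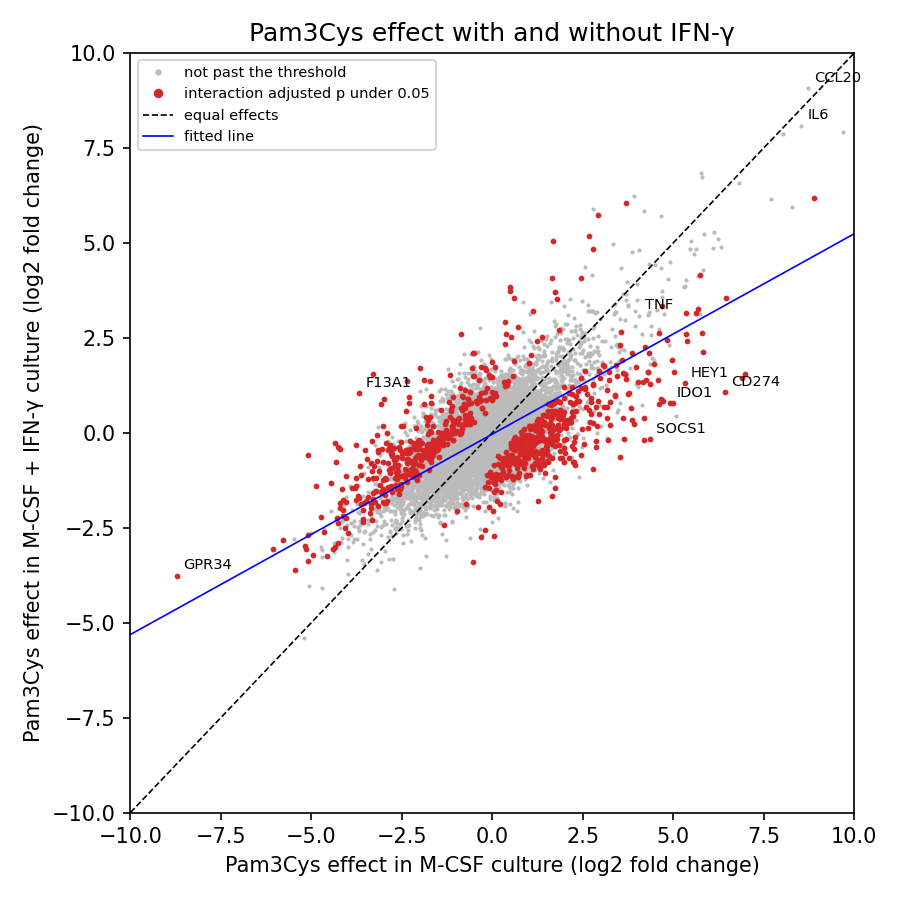
Log2 effect of Pam3Cys in M-CSF culture with IFN-gamma (vertical) against that without (horizontal), 1 point per gene. Red points have an interaction past the threshold, the dashed line marks equal effects and the solid line is the fitted line with a slope of 0.528.

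The effect of IFN-gamma was also set against the change during culture, since the series is about macrophage differentiation. Of the 1855 genes raised at least 2-fold by M-CSF culture, 367 were lower and 78 higher with IFN-gamma, where independence would give 110.0 and 116. Those 2 comparisons share the M-CSF arrays, which alone gives a negative relation: the covariance across genes was -0.337, and -0.0956 in simulated unchanged groups. The correlation was -0.38, and -0.50 (-0.53 to -0.47) in the simulated groups, where the shared arrays alone fix it near that value. Changes with culture also move the correlation, so the correlations do not show whether the relation was stronger or weaker than without an effect. The covariance of -0.337 lay below its simulated range of -0.111 to -0.0868, so array noise of the size simulated did not account for all of it. Between the culture change and the IFN-gamma effect under Pam3Cys, which share no arrays, the covariance was -0.130 against -0.000188 in simulation (r = -0.16 across genes). In that comparison 148 of the 1855 genes were lower and 117 higher, where independence would give 80.2 and 92.8, and of the 939 genes lowered at least 2-fold by culture 164 were higher and 54 lower, where it would give 47.0 and 40.6.

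Culture with both M-CSF and IFN-gamma was last compared with fresh monocytes. IDO1 rose by 8.08 ± 0.39, the interferon-induced gene IFI27 by 8.03 ± 0.45, the chemokine gene CCL2 by 7.51 ± 0.70, CD274 by 7.33 ± 0.21 and GPNMB by 7.48 ± 0.29. MRC1 and MAF rose by 4.12 ± 0.30 and 3.57 ± 0.20, and HES1 changed by -3.62 ± 0.37 (-3.21 ± 0.46 at its other probe set). RGS1, a regulator of G protein signalling, changed by -7.72 ± 0.31, FOSB by -8.01 ± 0.51, F13A1 by -7.51 ± 0.32 and EGR1 by -6.61 ± 0.51. Of 19 immediate early genes, 18 fell and 1 did not pass (0 higher and 18 lower adjusted over the list alone, limma camera adjusted p = 2.26e-17, and adjusted p = 0.124 with an estimated correlation). Of 24 macrophage differentiation genes, 11 rose, 3 fell and 10 did not pass (11 higher and 3 lower adjusted over the list alone, limma camera adjusted p = 0.0224, and adjusted p = 0.424 with an estimated correlation). Of 13 cholesterol synthesis and uptake genes, 11 rose and 2 did not pass (11 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 1.03e-04, and adjusted p = 0.424 with an estimated correlation). In all, 4468 genes passed the limma test, 2792 higher and 1676 lower, and 2771 changed at least 2-fold. With each array scaled to the same median the split was 1997 higher and 2418 lower.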

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

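The tests on HES1 were chosen after its result was seen, and the pattern itself was worded then, while the tests on the slope of the Pam3Cys effects were written before.

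For 839 genes the log2 effect of Pam3Cys differed with IFN-gamma by the limma interaction test, 395 with a positive and 444 with a negative interaction. The count was 334 without M-CSF replicate 1, 449 without M-CSF replicate 2, 424 without M-CSF+IFN replicate 2 and 425 without M-CSF+IFN+Pam replicate 2. Among interferon-induced and costimulatory genes the interactions were CD274 -5.36, SOCS1 -4.52, IDO1 -4.14, IRF1 -1.84, CD40 -2.69, CD80 -2.91 and ICAM1 -1.33, and of the 19 IFN-gamma response genes 1 had a positive interaction, 9 a negative one and 9 did not pass (2 higher and 10 lower adjusted over the list alone, limma camera adjusted p = 1.76e-05, and adjusted p = 0.576 with an estimated correlation). The sum of the single effects of CD274, and that of IDO1, would need a signal above 66608, the highest on any array. Their interactions may thus come in part from the top of the scale. Among receptors, adaptors and regulators of TLR signalling the interactions were TLR2 -0.86, TLR4 1.29, MYD88 -1.29, SOCS3 -1.36 and ATF3 2.23. Chemokine and cytokine genes had CXCL2 2.41, CXCL3 2.52, CXCL8 1.73, CXCL6 -1.59 and IL23A 2.35. Notch target genes had HEY1 -4.01, HES4 2.93 and HES1 2.00, and MHC class II genes CIITA 2.42 and HLA-DMB 1.71. CD93, S100A9 and MMP10 had -3.30, -2.09 and -3.51. Of 16 monocyte-enriched genes, 3 had a negative interaction and 13 did not pass (1 higher and 4 lower adjusted over the list alone, limma camera adjusted p = 0.152, and adjusted p = 0.602 with an estimated correlation). Of 24 macrophage differentiation genes, 2 had a positive one and 22 did not pass (2 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.176, and adjusted p = 0.576 with an estimated correlation), and of 16 macrophage transcription factor genes 3 and 13 (3 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.265, and adjusted p = 0.602 with an estimated correlation). Metabolic genes had LDHA -1.25, ASNS -2.70, PPA1 -4.39 and MAOA -4.23, and the remaining values were MYC -2.74, NR4A2 3.48, SLAMF1 -5.46 and NDP -5.44. The values of SELENOP 4.06, F13A1 4.72, GPR34 4.96, ATP6V0D2 3.88, DEPTOR 4.49 and ZNF704 4.84 came at least in part from the floor of the scale. The sum of the 2 single effects lay under the added constant of 17.24, as it did for 32 of the 395 positive interactions. Their full size therefore does not measure a different response. The part above that constant, a signal of 0, was 2.93 for ATP6V0D2, 2.07 for ZNF704, 2.03 for F13A1, 2.02 for DEPTOR, 0.52 for SELENOP and 0.36 for GPR34. Background signal was not taken off, so it may account for more of these values.

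Leaving out 1 array ended the limma interaction call of several of these genes. The highest adjusted p was reached without M-CSF replicate 1 for SOCS3 (0.13), TLR2 (0.15), ICAM1 (0.058) and TLR4 (0.060). It was reached without M-CSF replicate 2 for CXCL3 (0.13), CXCL8 (0.15), HES1 (0.17) and HLA-DMB (0.065), and without M-CSF+IFN replicate 2 for CD80 (0.11) and IL23A (0.13). Without M-CSF+IFN+Pam replicate 2 it was 0.096 for HES4, 0.051 for CXCL2 and 0.17 for CXCL6, and without M-CSF+Pam replicate 2 it was 0.11 for MAOA and 0.088 for MMP10. CIITA (0.12), ASNS (0.072), NDP (0.11), ATF3 (0.053) and S100A9 (0.054) kept the call with each array left out and lost it under 1 other setting each.

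Across genes, the slope of the Pam3Cys effect with IFN-gamma on that without was 0.528. A slope under 1 arises where responses are smaller, and also where they differ from gene to gene at the same overall size. Neither the slope nor the ratio below tells these apart. Noise on the arrays lowers a slope, so 1 donor's response with IFN-gamma was compared with the other donor's without, as a ratio to the covariance of both donors' responses without, which noise leaves near 1. This ratio was 0.601 (0.528 to 0.673 over both donor orders), which argues against noise as the whole cause. It was 0.582 (0.490 to 0.674) among 11528 genes that stayed under a signal of 5000, which argues against saturation as the cause across those genes. Brighter genes such as CD274 and IDO1 were left out there, so saturation stays open for them. Among 5018 genes whose level IFN-gamma alone moved by under 0.25 log2 the ratio was 0.810 (0.726 to 0.894), between the bounds set for that test. These genes were picked with the same M-CSF and M-CSF+IFN arrays that enter the ratio, so noise no longer cancels and pushes it up. The test thus left open whether levels already moved by IFN-gamma account for part of the difference. An action of IFN-gamma on the response itself, the difference the design names, stays open as a hypothesis that was not tested separately.

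HES1 rose by 1.72 with Pam3Cys alone and by 3.72 under IFN-gamma, an interaction of 2.00 at the brighter probe set. The limma adjusted p of this interaction was 0.0459 in the fit of genes and 0.0889 in a fit of all probe sets. At the other bright probe set the interaction was -0.555 (95% interval -1.99 to 0.879), which excludes 2.00, so the larger response may come from the choice of the probe set. The interval at the brighter probe set, 0.829 to 3.17, overlaps the other narrowly, and the difference between the probe sets was not tested. The lower HES1 level with IFN-gamma under Pam3Cys was -1.56 at the brighter probe set and -1.36 (-2.38 to -0.348) at the other, an interval below 0, which argues against the choice of the probe set for that decrease. The limma adjusted p of that decrease in a fit of all probe sets was 0.155 at the other probe set and 0.0410 at the brighter one. In the fit of genes the call was lost without M-CSF+Pam replicate 1 or M-CSF+IFN+Pam replicate 2. Without Pam3Cys the change with IFN-gamma was -3.56 at the brighter probe set and -0.81 (95% interval -1.82 to 0.207) at the other. That last interval holds 0, so the decrease without Pam3Cys rested on the brighter probe set. Why the probe sets differ was not tested, and the effect of IFN-gamma on HES1 stays open as a biological hypothesis.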

How the results depend on the processing

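The other HES1 probe set was the only alternative chosen after the results were seen. The total of genes past the threshold in each comparison stayed within 1.5 times its value under the alternatives that kept all arrays, while median scaling turned the split of higher and lower genes in 4 of them. The exceptions were that a prior variance without trend gave 1055 in place of 1668 genes for IFN-gamma in M-CSF culture, 814 in place of 1275 for IFN-gamma under Pam3Cys and 305 in place of 839 for the interaction, and the replicate block, which pairs the arrays by donor, gave 1304 for the interaction. The block ended no call among the 742 named pairs or the 85 lists, and added calls for 58 named pairs that had not passed, of which 1 was in the selection for the text, MRC1 with Pam3Cys (-0.81, limma adjusted p = 0.0556, and 0.0279 with the block). With an estimated correlation 0 of the 85 list calls held (by fry, 63 did), without trend 69, and with probe sets of the suffix _x_ or _s_ left out 68. Leaving out 1 array gave 2963 to 4514 genes for M-CSF culture, 697 to 1751 for IFN-gamma, 3210 to 4668 for Pam3Cys, 1822 to 3128 for Pam3Cys under IFN-gamma, 761 to 1260 for IFN-gamma under Pam3Cys, 334 to 703 for the interaction and 3189 to 4572 for culture with M-CSF and IFN-gamma. The lowest counts were reached without M-CSF replicate 1, except those for Pam3Cys under IFN-gamma (M-CSF+IFN replicate 1), IFN-gamma under Pam3Cys (M-CSF+IFN+Pam replicate 2) and the last (fresh replicate 1). These fits also have fewer degrees of freedom.

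The correlation of the Pam3Cys effects (0.692) was 0.630 with a pseudocount of 1, 0.737 with 4 times the constant, 0.618 with no filter, 0.778 with the filter at the 70th percentile, and 0.629 to 0.692 with 1 array left out. The covariance of the culture change with the IFN-gamma effect under Pam3Cys (-0.130) was -0.169, -0.0915, -0.0903 and -0.175 under these 4 settings, and -0.146 to -0.114 with 1 array left out. With the IFN-gamma effect that shares arrays (-0.337) it was -0.473, -0.229, -0.282 and -0.369, -0.353 with quantile normalization, and -0.439 to -0.315 with 1 array left out. The sign held in each. A larger pseudocount draws dim genes together by construction.

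Some single genes turned in sign. TNIP1 with Pam3Cys was 3.56, and -0.23 without the suffixes _x_ and _s_. The HES1 interaction was 2.00, and -0.55 at the other probe set. None of the others had passed on the probe set used. HES1 in M-CSF culture was -0.06, and -0.47 to 0.35 with 1 array left out, highest without M-CSF replicate 1, but it was -2.40 at the other probe set (limma adjusted p = 0.00334). HEY1 with IFN-gamma was -0.26, and -0.73 to 0.21. IL12B with IFN-gamma was 0.16, -0.11 with a pseudocount of 1, and -0.61 to 0.92 with 1 array left out. CSF1R with Pam3Cys was -0.18, and 0.14 with median scaling. CXCL10 with Pam3Cys under IFN-gamma was 0.17, -0.11 with quantile normalization, and -0.10 to 0.45 with 1 array left out. The IL6 interaction was -0.45, 0.53 with 4 times the constant and -1.62 (limma adjusted p = 0.018) with a pseudocount of 1. The cause was not tested for these genes.

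Of 742 named pairs past the threshold, a prior variance without trend ended 108 calls, the mean over probe sets 89 (3 more turned), fitting only the arrays compared 43, leaving out _x_ and _s_ probe sets 35 (8 more turned), no filter 33, median scaling 30, a pseudocount of 1 17, quantile normalization 14 and 4 times the constant 6. In the selection for the text the calls that were lost or turned under any setting were ITGAM and IL10 in M-CSF culture; MITF, MRC1, CXCL2, SERPINA1, TLR2, HLA-DOA, CYC1 and HES1 with IFN-gamma; IL1A, NRARP, TNIP1 and XBP1 with Pam3Cys; IL1A, HEY1 and IFIT2 with Pam3Cys under IFN-gamma; SELENOP, HES1, TNF, IL23A, MMP10, MMP19, TIMP1, CXCL5, CCL23, TNIP3, PFKFB3 and SOCS3 with IFN-gamma under Pam3Cys; and 20 of the interactions. Signals near background limit fold changes, since the added constant of 17.24 then sets their size.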

Other observations

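Both tests on PPBP were chosen after its result was seen, and the second after the first had been run.

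Other gene lists were tested with Pam3Cys in M-CSF culture. Of 11 measured genes of M-CSF receptor and growth factor signalling, 7 rose and 4 did not pass (7 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 6.14e-04, and adjusted p = 0.130 with an estimated correlation). Of 15 genes of the unfolded protein response, 8 rose, 1 fell and 6 did not pass (8 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 2.72e-04, and adjusted p = 0.355 with an estimated correlation), with the asparagine synthetase gene ASNS at 4.31 ± 0.26. Of 13 cholesterol synthesis and uptake genes, 6 rose and 7 did not pass (6 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.0147, and adjusted p = 0.724 with an estimated correlation), for example HMGCS1 at 1.97 ± 0.20 and LSS at 2.22 ± 0.37 (± SE, n = 2). Of 15 cell cycle genes, 5 fell and 10 did not pass (0 higher and 5 lower adjusted over the list alone, limma camera adjusted p = 0.106, and adjusted p = 0.419 with an estimated correlation), with MCM6 at -2.41 ± 0.22 and PCNA at -1.11 ± 0.21. Of 11 dendritic cell markers, 2 rose, 4 fell and 5 did not pass (2 higher and 5 lower adjusted over the list alone, limma camera adjusted p = 0.867, and adjusted p = 0.997 with an estimated correlation), with the migration receptor gene CCR7 at 3.56 ± 0.34 and LAMP3 at 6.09 ± 0.28. Of 7 T cell markers, 1 rose, 2 fell and 4 did not pass (1 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 0.918, and adjusted p = 0.997 with an estimated correlation), with the receptor chain gene IL7R at 6.24 ± 0.24, and the list's median turned from -0.15 to 0.17 with median scaling. EBI3, a subunit of cytokines of the IL-12 family, rose by 8.29 ± 0.52 and the chemokine receptor gene CX3CR1 changed by -4.71 ± 0.56.

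PPBP had a signal of 437 in fresh monocytes, 14419 in M-CSF culture, 6.10 with IFN-gamma, 12246 with Pam3Cys and 18.7 with both. PPBP is abundant in platelets, which adhere to monocytes and can pass a bead selection for CD14. The median change with IFN-gamma of 7 other platelet markers was -0.632 (quartiles -1.21 to -0.0767), but 5 of the 7 were too dim in M-CSF culture (signals of the 7 from 11.9 to 341) to fall by 3 log2, so this test left the loss of platelets open. Platelets carried over would also have to explain the rise from fresh monocytes, where PPBP changed by 4.99. The other markers had a median of 0.716 (quartiles -1.05 to 1.10), which argues against platelets as the cause of the high level. These markers did not move together. TREML1, GNG11, ITGA2B and SPARC went the way of PPBP, by 1.64, 1.13, 1.06 and 0.716 with culture. With IFN-gamma they changed by -1.34, -1.08, -0.63 and -1.82. PF4, TUBB1 and MYL9 changed by -1.31, -1.77 and -0.78 with culture and by -0.34, 0.19 and 1.59 with IFN-gamma. Expression of PPBP by the macrophages themselves, lowered by IFN-gamma, may explain both changes and was not tested, nor was how many of the 7 markers macrophages express.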
